A study of Mus musculus with 6 samples.

How the data were processed

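RNA abundance in the spleen of C57/B6 mice was measured on 6 single-channel arrays, 3 after sham laparotomy and 3 after cecal ligation and puncture (CLP), all from samples taken 24 h after surgery. Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was used. The array, the scanner, the background correction, the normalization and the authors' own test are not given in the sources used here.

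The deposited table holds 1 spot intensity per probe and array, on a linear scale, in whole numbers from 0 upward. It lists 597 probes. All but 9 fall into 6 lettered blocks (A to F) of 98 probes, with IDs made of the block letter, a number and a further letter, and the 9 have IDs of G and a number. The 2 replicate 1 columns hold values for all 597 probes and the 2 replicate 2 columns for 593. The 2 replicate 3 columns hold values for the first 157 probes of the table, A1a to B5c, so that 154 probes had values on all 6 arrays. The highest intensity occurred more than once on 5 of the 6 arrays, as at a detector ceiling, and exact 0 occurred on 5 of the 6 arrays. No column of another sample was in the table (0 columns).

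No table that pairs these probe IDs with genes was used here. Of the 597 IDs, 19 coincide with a symbol, locus tag or synonym in the mouse gene table, as short strings will, and these matches were not used. Gene lists for cytokines, chemokines, acute phase proteins, apoptosis, cell cycle, heat shock, spleen cell types and neighbouring tissues had been fixed before the data were examined, together with all settings described as planned. None of their genes could be assigned to a probe, so the planned tests of gene lists were not made, and the text reports probes by ID.

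The intensities were changed to log2(intensity + 1214.6), the pseudocount being the 10th percentile of all positive values. Fold changes on this scale understate the change of dim probes. Array medians over all measured probes differed by up to 2.13-fold, and over the 154 shared probes by up to 1.64-fold. By the rule fixed beforehand (quantile normalization where medians differ by more than 1.2-fold), arrays were quantile normalized in limma 3.58.1 under R 4.3.3. This step treats the 157 probes of the replicate 3 arrays as a sample of the whole array. On the replicate 1 arrays these probes had a median intensity of 8799 against 5017 for the others, so the step can lower the replicate 3 values; both groups hold 1 such array. Normalization over the 154 shared probes alone was therefore added after the data were seen.

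A probe was tested if it was above 0 on at least 3 arrays and on at least 2 of 1 group, with at least 2 values in each group. This kept 594 probes, 154 with 3 values per group and 440 with 2, and left out 3. The test was limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 594 probes and a threshold of 0.05. All 6 arrays entered 1 fit without further terms. Confidence intervals are at 95% and come from the same fit. They take no account of probes being picked for a small p. Further summaries needed no model of the spread, namely the count of probes whose groups did not overlap, the sign of the change within same-numbered arrays, and correlations between arrays. The number of arrays limits the precision. An exact permutation of 3 against 3 cannot give a two-sided p below 0.1, and one of 2 against 2 cannot give one below 0.333. The labels do not say whether each sample is 1 animal, so p-values measure only the spread between these samples, which may be technical.

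Replicate numbers pair the samples by the data. After quantile normalization, deviations from the group means over the 154 shared probes correlated between sham and CLP arrays of the same number at 0.56 for replicate 1, 0.64 for replicate 2 and 0.75 for replicate 3, against -0.61 to 0.04 for arrays of different numbers. Deviations within a group cancel out for each probe, so high values for the same number lower the others by arithmetic. The contrast between them is thus not separate evidence. The same-numbered columns also lack the same probes. No label states what a number marks. A fit with the replicate number as a block was planned as an alternative and is given beside the results it moves.

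The rule for naming, fixed beforehand, took probes with a single gene name past the adjusted threshold whose groups did not overlap, and then filled up by smallest unadjusted p. Since no probe had a gene name, that condition was dropped. The rule also asked for more probes in each direction, and the cut to 2 was not part of it. Named are the 2 probes with the smallest unadjusted p in each direction among those whose groups did not overlap. Others that are named were chosen after their values were seen.

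The alternatives chosen before the data were examined were median scaling over the shared probes, no scaling, no pseudocount, a pseudocount 4 times as large, no filter on dim probes, only probes brighter than the median probe, a trended and robust eBayes step, an unmoderated equal-variance test per probe, the replicate block, Spearman correlation, and leaving out each array in turn. The fit was tested on simulated data with the real missing values and probe means. Spreads were drawn at random from those of all tested probes, so they were not matched to a probe or its level. Errors were independent between probes, and no normalization or detector ceiling was simulated, so the rates may not hold for the real arrays. In 20 simulations of 594 probes with 30 changed, the fit without a block called 65.8% of log2 changes of 3, 34.6% of changes of 2 and 7.08% of changes of 1. The fit with the block called 33.3%, 16.7% and 11.7%. With 200 changed probes, the fit without a block called 87.9%, 74.6% and 41.3%, and the fit with the block 91.2%, 81.2% and 59.4%. Among unchanged probes, with 30 changed, an unadjusted p under 0.05 came up for 2.51% without the block and 6.60% with it. Figures were drawn with matplotlib 3.10.9.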

Results

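Sepsis was modelled by cecal ligation and puncture, in which the cecum is tied off and pierced so that gut bacteria leak into the abdomen, and the control was a laparotomy without it. The series title sets splenic against hepatic responses. The 6 arrays described here are all from spleen, the secondary lymphoid organ that filters blood, and liver was not analysed here. They comprise 3 sham and 3 CLP samples, each taken 24 h after surgery. The median intensity over the 154 probes measured on all 6 arrays was 8788, 10035 and 7099.5 on the sham 1, 2 and 3 arrays and 8808.5, 11520.5 and 11663 on the CLP 1, 2 and 3 arrays. Replicate 3 of both groups was measured for 157 of the 597 probes, so that 440 probes rest on 2 arrays per group. Between 0 and 13 values per array were 0. Of the 9 probes with a G number, 3 (G5, G19 and G21) were saturated at the highest intensity on every sham and CLP array that measured them, and no fold is given for them.

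The comparison of CLP with sham spleen asks which transcripts differ 24 h after the onset of peritoneal sepsis. On the log2 scale used here, which understates the change of dim probes, the largest difference was at probe F3g. It gave intensities of 1464 and 1993 in the sham 1 and 2 spleens and 45029 and 44126 in the CLP 1 and 2 spleens. Within the same-numbered arrays this is a ratio of 30.8 and 22.1 in deposited intensities, without scaling between arrays. On the quantile normalized log2 scale with the pseudocount, the mean change corresponds to 12.5-fold. Probe B1a was near the floor in all 3 sham spleens, at 470, 0 and 388, and read 3232, 6224 and 12370 in the 3 CLP spleens. In the other direction, probe F3a read 41467 and 36412 in sham against 15331 and 15625 in CLP. Probe B3e read 18009, 17812 and 17369 in sham against 8610, 9287 and 14296 in CLP. The genes these probes detect are not given in the sources used here.

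None of the 594 tested probes passed an adjusted p of 0.05 in limma (0 probes), so no single probe is called changed. At an unadjusted p under 0.05, limma gave 80 probes, 47 higher and 33 lower in CLP, where the nominal 5% of 594 is 29.7. Without CLP 1 the count was 42, 21 in each direction, and without CLP 2 it was 52, 30 higher and 22 lower. In simulated data with paired arrays, independent probes and 30 changed probes, this fit gave such a p for 2.51% of the unchanged probes. Real probes can vary together, so this rate does not show how far the count can move without a change. The unmoderated test per probe also gave 0 after adjustment and 68 before it. The smallest adjusted p was that of F3g, 0.0635, with a log2 change of 3.64 ± 0.18 (SE, n = 2 per group; 95% interval 3.10 to 4.19). It was 2.72 with a pseudocount 4 times as large and 4.27 with none, both outside that interval. The change was -0.99 ± 0.16 for B3e (SE, n = 3 per group; interval -1.40 to -0.58) and -1.46 ± 0.19 for F3a (SE, n = 2 per group; interval -2.02 to -0.90). For B1a, whose sham values all lie below the pseudocount of 1214.6, the pseudocount sets the size of the log2 change. It was 1.997 as reported, 0.99 with a pseudocount 4 times as large and 4.02 with none, higher in CLP each time. B1a, B3e and F3a had a limma adjusted p of 0.121. Over the alternatives that leave out no single array, in limma or the unmoderated test, the adjusted p ranged from 0.0165 to 0.163 for F3g, 0.0283 to 0.195 for B1a, 0.0424 to 0.205 for B3e and 0.0468 to 0.225 for F3a. Without CLP 1 the limma adjusted p of all 4 was 0.612. F3g in the CLP arrays stood at 91.0% and 86.0% of the array's highest intensity, where the scale is compressed.

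**Figure D1:**
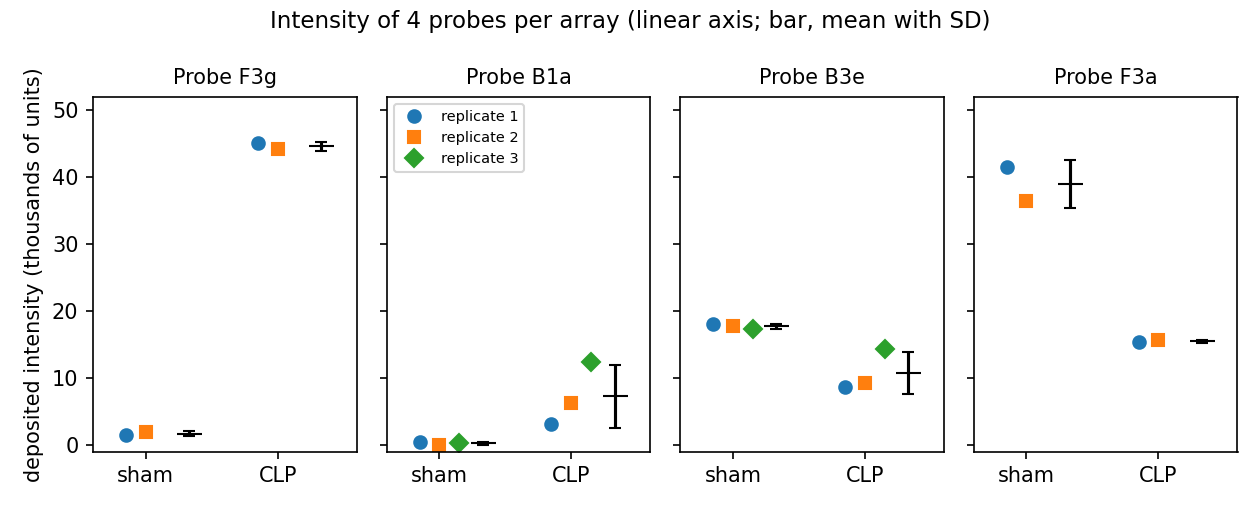
Deposited intensity, on a linear axis, of probes F3g, B1a, B3e and F3a on each sham and CLP array; symbols mark replicates 1 to 3, and the bar beside them is the mean with SD. F3g lay at 1464 and 1993 in sham and at 45029 and 44126 in CLP, while F3a lay at 41467 and 36412 in sham and at 15331 and 15625 in CLP.

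The split by direction depended on the scaling. Without any scaling, limma gave 96 probes at an unadjusted p under 0.05, 80 higher and 16 lower in CLP, and 6 past the adjusted threshold, all 6 higher. With arrays scaled to a common median it gave 74, 52 higher and 22 lower, and 8 past the adjusted threshold, all 8 higher. The median log2 change over all tested probes was 0.14 without scaling and -0.05 after quantile normalization, relative to which the changes are given.

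Same-numbered sham and CLP arrays deviated together, and the fit with the replicate number as a block gave 128 probes at an unadjusted p under 0.05, 66 higher and 62 lower in CLP, with 0 past the adjusted threshold in limma (smallest adjusted p 0.0835). In the same simulations it gave such a p for 6.60% of the unchanged probes. Over the 154 probes measured on all 6 arrays and normalized by themselves, an alternative chosen after seeing the data, the fit with the block called 10 probes, 6 higher and 4 lower, and the fit without it called 0. B1a and B3e were among the 10, with a limma adjusted p of 0.0283 and 0.0424. B3e changed by -0.90 ± 0.13 (SE, n = 3 pairs), and the size for B1a depends on the pseudocount as above.

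Across probes, the change in pair 1 and the change in pair 2, which share no array, correlated at r = 0.57 (Spearman 0.54, 591 probes, which are not independent replicates). Pair 1 against pair 3 gave r = 0.56 and pair 2 against pair 3 gave r = 0.46. All 3 pairs had the same sign for 92 of the 154 probes measured in all, 39 higher and 53 lower in CLP. That is 59.7%, where independent signs in each pair give 25% on average. Probes can vary together, so this rate does not show how far the share can move without a change. Of 437 probes measured in pairs 1 and 2 alone, 310 had the same sign (142 higher and 168 lower). These are 70.9%, where independent signs give 50%, with the same limit. All signs were counted after quantile normalization, where the median log2 change over all tested probes was -0.05. It was 0.14 without scaling, where signs were not counted. The split into higher and lower is therefore not read as a result.

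**Figure D2:**
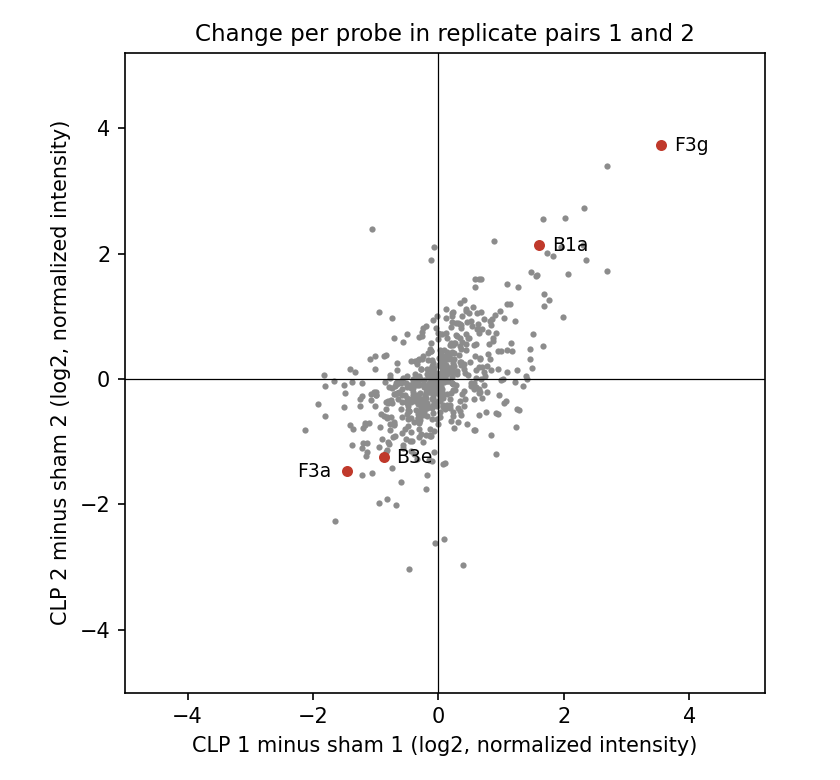
Log2 change of each of 591 probes in replicate pair 1 (CLP 1 minus sham 1, horizontal axis) and pair 2 (CLP 2 minus sham 2, vertical axis), after quantile normalization; each point is a probe, and red points are the 4 named probes. Points lie along the rising diagonal (r = 0.57), with F3g farthest to the upper right.

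The groups did not overlap for 32 of the 154 probes with 3 values each, 18 with CLP higher and 14 with CLP lower. This is 20.8%. Chance gives 10% where the 6 arrays are exchangeable, which paired arrays are not. With these probes normalized by themselves the count was 29, and the other 3 splits that part all same-numbered pairs gave 7, 3 and 1, while the 6 splits that keep 2 pairs together gave 12 to 27. Without scaling the count was 40, 35 higher and 5 lower. For the 440 probes with 2 values each, 190 did not overlap, 93 higher and 97 lower, which is 43.2%, against 33.3% for exchangeable arrays. Without scaling these were 134 higher and 60 lower, and with median scaling 99 higher and 70 lower.

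A mean log2 change of at least 1 was seen at 37 probes with CLP higher and at 22 with CLP lower. Of these, 36 and 20 had groups that did not overlap. Selection for a large mean change makes this likely by itself, most of all with 2 values per group, so these counts add no support. The probes changed by at least 1 were spread unevenly over the lettered blocks, a comparison made after seeing the data. Block F held 14 of the 37 higher probes and 1 of the 22 lower ones among its 98 probes. Block D held 1 higher and 9 lower among its 98. Fisher's exact test of each block against the other 5, two-sided, gave an adjusted p over 12 tests of 0.0144 for the higher probes of block F, 0.0324 for the lower probes of block D and 0.0482 for its few higher probes. Every other block had an adjusted p of 0.224 or more. In pair 1 alone, block F had 18 probes higher and 5 lower by at least 1, where no other block had more than 10 higher. In pair 2 it had 13 higher and 4 lower, where block C also had 13 higher and block E had 10. Its count of higher probes thus stood out in pair 1 and not in pair 2. Block D had 4 higher and 6 lower in pair 1, where blocks A, B and E had 7, 6 and 12 lower, and 1 higher and 15 lower in pair 2, where no other block had more than 10 lower. Its count of lower probes thus stood out in pair 2 and not in pair 1. Without scaling, block F had 18 higher and 1 lower, and block D 2 higher and 7 lower. The test takes probes as independent, and neighbouring probes were correlated, so these p-values are too small. It also pools blocks whose means rest on different numbers of arrays. Most of block A and part of block B were measured on all 6 arrays, and blocks C to F on replicates 1 and 2 alone. A mean over fewer arrays varies more, so noise alone reaches a change of at least 1 more easily in blocks C to F. The Fisher test cannot separate this from a difference between blocks, and blocks C to F were not tested among themselves. What the blocks hold is not given in the sources used here.

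The mean correlation between arrays was highest for those of the same replicate number. Over the 154 shared probes, the mean Pearson correlation of normalized log2 intensity was 0.857 ± 0.050 (SD, 3 pairs of arrays) between sham and CLP of the same number. It was 0.807 ± 0.068 (SD, 6 pairs) within a group and 0.734 ± 0.066 (SD, 6 pairs) for arrays that shared neither. The lowest of the 15 values was 0.612, between sham 2 and CLP 3, and the highest was 0.904, between CLP 1 and CLP 2. The difference between sharing a number and sharing a group is about the size of the spread, and it was not tested.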

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

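The 4 named probes kept the sign of their change under all alternatives run for each (16 for F3g, 17 for B1a, 18 for B3e and 16 for F3a). F3g passed the adjusted threshold in 6 of the 10 that leave out no single array, B1a in 2 of 11, B3e in 2 of 12 and F3a in 1 of 10, and none passed when 1 array was left out. The count past the adjusted threshold, 0 as reported, was 8 with median scaling, 6 without scaling, 1 with a pseudocount 4 times as large, 9 among the 297 brighter probes (5 higher and 4 lower) and 3 with a trended and robust eBayes step. With both replicate 3 arrays left out, chosen after seeing the data, it was 1. The cause was not tested. The brighter probes are fewer tests, 297 against 594, but the limma adjusted p of F3g fell from 0.0635 to 0.0167 among them. That is more than fewer tests alone can give. It stayed 0 with no pseudocount, no filter and the unmoderated test, and when any 1 array was left out (0 to 0). Where this left a group with 1 value, the spread came from the probe's other group, moderated towards that of all probes, and the lone value was assumed to vary like it. The replicate block left it at 0 over all 594 probes but moved the count at an unadjusted p under 0.05 from 80 to 128. With only the probes on all 6 arrays these counts were 21 without the block and 47 with it, and the block gave 10 probes past the adjusted threshold. Without single arrays the count at an unadjusted p under 0.05 ranged from 42 to 87, falling to 42 without CLP 1 and 52 without CLP 2. The count of probes whose groups did not overlap ranged from 41 to 63 of 154 (20% by chance for 3 against 2), being 63, of which 43 lower, without sham 3. For 2 against 2 it was 103 of 206 among the brighter probes and ranged from 191 to 324 without single arrays, the higher values being for 2 against 1, where chance gives 66.7%. Mean correlations between arrays were lower among the brighter probes, at 0.763 for the same number, 0.693 for the same group and 0.535 for neither. They ranged from 0.837 to 0.887, 0.780 to 0.837 and 0.714 to 0.767 without single arrays, and the order of the 3 kinds was the same. Intensities at 0 or at the ceiling limit how far a change can be measured.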

Other observations

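The tests of brightness, of row and column effects as the whole cause, of the share of variance between columns and of changes and sham levels along rows and columns were chosen after the result was seen. Chance cannot be excluded by regrouping arrays, because 3 against 3 make only 10 splits. The real split gave 80 probes at an unadjusted p under 0.05 and the highest other gave 62, so 1 of the 10 splits gave as many. Over the 154 probes measured on all 6 arrays, normalized by themselves, the real split gave 21 such probes, and the split of sham 1, sham 3 and CLP 3 from the rest, which keeps the replicate 2 and 3 pairs together, gave 24. The count past the adjusted threshold was 0 in all 10 splits, with a highest other of 0. Of the 4 splits that part all 3 same-numbered pairs, fitted with the replicate block, 1 gave as many as the real 128, and the highest other gave 75.

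Replicates 1 and 2 differed in the same way in sham and CLP spleens. The difference between replicates 2 and 1 correlated across 593 probes at 0.65 between the groups as deposited. For 28 probes it had the same sign in both groups and reached at least 1 on the log2 scale in each, 23 of them higher in replicate 2. Probes B2k and D3i, chosen after their values were seen, are examples. B2k read 0 and 165 on the sham 1 and CLP 1 arrays and 20244 and 36625 on sham 2 and CLP 2, while D3i read 11285 and 7437 against 531 and 0. The correlation was 0.60 after quantile normalization. This value cannot decide on the overall brightness of the arrays. A uniform difference in brightness adds nearly the same amount to every log2 difference and barely moves such a correlation. Reading an ID as block, row and column, the difference correlated at 0.24 between probes that follow each other in a column (permutation p = 1e-04, the smallest 10000 shuffles can give; adjusted 7e-04 over 7 neighbour tests), and 33.3% of its variance lay between columns of blocks against 16.9% at the 95th percentile of shuffles. Between probes that follow each other in a row it correlated at -0.019 (permutation p = 0.601). These values point to a part that goes with the column of an ID. They do not show an uneven background that also varies smoothly along rows. Additive effects of rows and columns as the whole cause are argued against, since the correlation was still 0.56 after the means of rows and columns of each block were removed. Local patches or effects of single spots would survive that step, so position as the whole cause stays open. A difference between the animals or days behind the numbers stays open, as no label describes one.

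After CLP, probes of neighbouring IDs within a row changed together. The mean change in pairs 1 and 2 correlated at 0.23 over 539 neighbours (permutation p = 8e-04, adjusted 0.0028) but at 0.08 along columns (permutation p = 0.589). The 95th percentile of shuffles within blocks was 0.158 along rows and 0.162 along columns. The probes before F3g, F3e and F3f, chosen after their values were seen, had log2 changes of 3.04 and 2.53, while F3h, after it, had -0.04. The correlation was not computed without F3e, F3f and F3g. How far the row correlation rests on this run is therefore not known. The replicate difference correlated at -0.019 along rows, which leaves uneven background open, since a background that differs between CLP and sham arrays cancels in that difference and the prediction had not allowed for it. Signal spreading from a bright spot cannot be told apart from a layout that places related genes side by side. Among 120 neighbours under 10000 units the correlation was 0.26, as large as over all neighbours, but below the 95th percentile of shuffles of 0.30. The sham level also correlated along rows, at 0.19 (adjusted permutation p = 0.00583). No biological explanation was tested, since the probes' genes were not known here.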
